A study of Mus musculus and Homo sapiens with 352 samples.

How the data were processed

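The series covers 352 samples in 98 groups, 243 of them Hi-C, from mouse cells (184 samples) and an established human cell line (168 samples). Analysed here were 2 lists of CTCF ChIA-PET interactions, 1 from wild-type CH12 cells and 1 from CH12 cells with a CTCF mutation that the labels place at zinc fingers 9 to 11, and 2 lists of CTCF ChIP-seq peaks, 1 from wild-type CH12 cells and 1 from resting and activated B cells. The other samples were not analysed here. Groups were taken from the sample labels.

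The interaction lists hold counts of supporting tags per interaction as the authors deposited them. Per the file headers, interactions were mapped to CTCF peak calls with core motifs and kept with 3 or more supporting tags and a loop size of at most 2 Mb. The CH12 peak list holds 1 score per peak, deposited by the authors, with peak names that begin with MACS. The B cell list, deposited in the narrowPeak layout, holds a fold over background and a −log10 q-value per peak. Whether libraries were pooled before peaks were called is not given in the sources used here. Per the submitters' processing notes the build was mm9, and the tools listed for the ChIA-PET libraries were CASAVA 1.8.2, Bowtie 1.1.1, SAMtools 1.2, bedtools 2.25 and BWA, without their roles. The interaction caller, and the cells whose CTCF peak calls set the anchors of each list, are not given in the sources used here, so an interaction can be missing from a list for lack of a peak call as well as for few tags.

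There was 1 ChIA-PET library per genotype. No difference has a replicate check, and every comparison is between 2 libraries, not between genotypes. The lists leave out interactions under 3 tags, so the sum of listed tags is not the depth of a library, which is not given in the sources used here. Wilson and exact 95% intervals cover counting error only, and they treat interactions or tags as independent. Block intervals came from 1000 resamples of 10 Mb blocks of the genome and cover variation between regions of these libraries only.

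Interactions matched when both anchors overlapped by at least 1 bp. Chance levels came from 100 circular shifts along each chromosome and, added after the data were seen, from 100 moves along the ordered anchors of both lists. Span was the distance between anchor midpoints. An anchor was called one-sided when all of its partners, 3 or more, lay on 1 side. The share of matches expected if both libraries sampled the same rates was estimated from a mixture of truncated Poisson distributions fitted to the tags of each list. Tags of single interactions were compared with a two-sided exact binomial test at the ratio of all listed tags, with Benjamini-Hochberg adjustment at 0.05; an interaction missing from a list was given 2 tags, the most that the limit of 3 tags allows, although one missing for another reason could have had more. This test was chosen after the data were seen. Peak scores were used as ranks within their own list, apart from 1 CH12 score that is set beside the lowest score of its list.

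Named interactions were the 5 with most tags among those in the wild-type list only, in both lists and in the mutant list only. Named anchors were the 3 with most partners in each list, and named peaks the 3 highest of each peak list that overlapped the other list and the 3 highest that did not. This rule, the main comparisons and most alternatives were fixed before the data were examined. Alternatives were better supported interactions (4 tags or more), other overlap rules, lists of equal length, a span limit, stronger peaks, other partner numbers and wider merging of anchors. Gene lists at anchors and the orientation of CTCF motifs were planned and not run, since no mm9 annotation or sequence was used here.

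The steps were tested on simulated data. For the count test, 200 of 14850 interactions were changed in the second library, all drawn from those with a mean of 10 or more tags. It recovered 88.1% of those made 4-fold higher and 19.2% of those made 4-fold lower, which held fewer tags in all. It called 1 unchanged interaction. Recovery among interactions with fewer tags, which were most of each list, was not tested. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.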

Results

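CTCF-anchored chromatin interactions were measured by ChIA-PET, which sequences pairs of DNA ends ligated within chromatin pulled down with an antibody, in CH12 cells, a mouse B cell lymphoma line. One library came from wild-type cells and 1 from cells with CTCF mutated at zinc fingers 9 to 11. CTCF is a zinc finger protein that binds DNA at a directional motif and marks the ends of many chromatin loops. The wild-type list held 11534 interactions with 74198 tags, and the mutant list 11820 interactions with 82222 tags. The median was 4 tags per interaction in the wild-type list and 5 in the mutant list. CTCF binding sites came from 39438 peaks of wild-type CH12 cells and 59978 peaks of resting and activated B cells. All coordinates are in mm9. Neither genotype had a replicate ChIA-PET library, so the differences below are between 2 libraries.

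The first comparison asked whether the mutant list held fewer interactions. The ratio of wild-type to mutant interactions was 0.976 (95% exact interval 0.951 to 1.00), and that of tags was 0.902 (0.893 to 0.911). Both intervals treat interactions or tags as independent. Many interactions were in both lists and tags fall together within interactions, so the intervals are only approximate. The wild-type interactions joined 13547 anchors and the mutant interactions 12476 anchors, of which 9095 were in both lists. An anchor had a mean of 1.70 partners in the wild-type list and 1.89 in the mutant list. By chromosome, the mutant share of tags over the wild-type share was lowest on chromosome X, at 0.683, and on chromosome 16, at 0.779. It was highest on chromosome 17, at 1.15.

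The lists shared 5400 interactions with identical anchors. These were 46.8% of the wild-type interactions (95% Wilson interval 45.9 to 47.7) and 45.7% of the mutant interactions (44.8 to 46.6). Circular shifts matched at most 0.0434% of the wild-type interactions. Moves along the ordered anchors, a closer chance level, matched a mean of 12.8% and at most 13.7%. Missing from the other list were 53.2% of the wild-type and 54.3% of the mutant interactions, where the mixture fitted to the tags gave 32.9% and 38.8% at equal rates. Whose CTCF peak calls set the anchors is not given in the sources used here, so a missing interaction can also reflect a missing peak call. Among interactions with both anchors in use in the other list, a restriction that keeps every match and so raises the share, 78.6% (77.6 to 79.5) of the wild-type and 66.6% (65.6 to 67.7) of the mutant interactions were matched. Interactions with many tags were shared more often. Among wild-type interactions with 3 tags, 26.9% were in the mutant list, against 90.0% (86.8 to 92.6) of the 412 with 20 or more tags. Among mutant interactions with 20 or more tags, 92.5% (90.0 to 94.5) of 534 were in the wild-type list. Across the shared interactions the log2 tags of the libraries had a Pearson r of 0.604 and a Spearman rho of 0.527; interactions are not independent replicates.

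**Figure D1:**
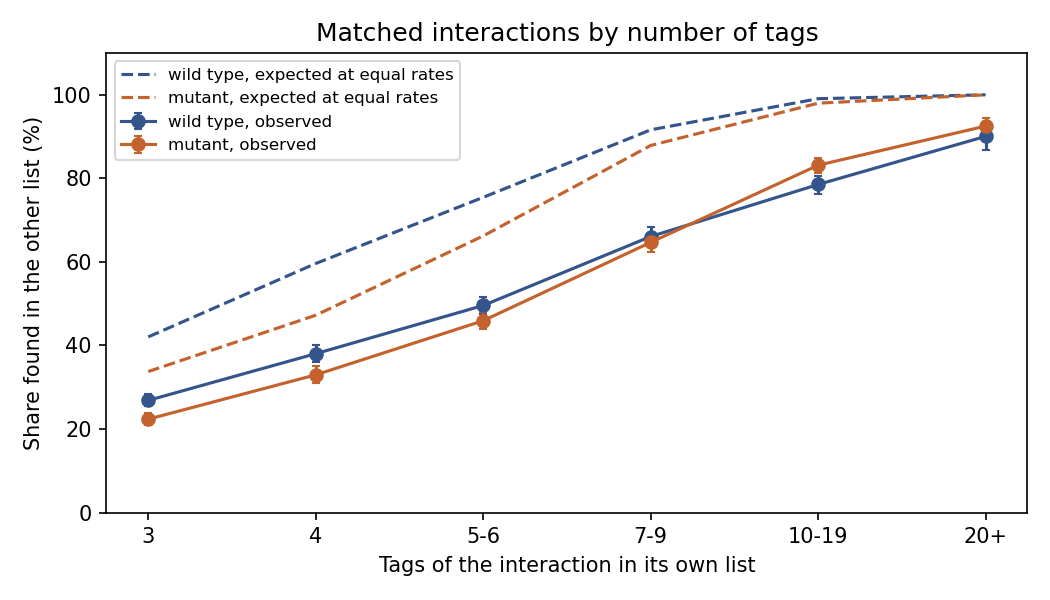
Share of interactions found in the other list (y axis, %) by the number of tags in their own list (x axis), with 95% Wilson intervals; dashed lines give the share expected if both libraries sampled the same rates. The observed share rose from 26.9% at 3 tags to 90.0% at 20 or more in the wild-type list and stayed below the dashed line throughout.

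By the exact binomial test with Benjamini-Hochberg adjustment, which compares these 2 libraries and not the genotypes, 177 of 17954 interactions differed beyond counting error. Of these, 105 had more tags in the wild-type library and 72 in the mutant library. Scaling by the tags of shared interactions gave 128 and 66, testing shared interactions alone gave 40 and 35, and testing those with both anchors in both lists gave 70 and 62. Of the 177, 110 were missing from 1 list and rest on the 2 tags given to them. In simulated counts, changes were made only to interactions with a mean of 10 or more tags. There the test recovered 88.1% of interactions made 4-fold higher and 19.2% of those made 4-fold lower in the second library. Only the second library was changed, so those made lower held fewer tags in all. The simulation therefore does not show whether the counts by direction are comparable. Among interactions of the wild-type list only, the one with most tags joined chromosome 2 positions 166897176 to 166898269 and 167044651 to 167045629, with 72 tags over 147 kb. It was followed by interactions on chromosome 6 (50757826 to 50758758 with 50886656 to 50887853, 52 tags), chromosome 7 (19885700 to 19886774 with 19927819 to 19929603, 38 tags), chromosome 11 (117944357 to 117945880 with 117963645 to 117966093, 37 tags) and chromosome 12 (32652066 to 32653185 with 32829162 to 32830017, 36 tags). Among interactions of the mutant list only, the one with most tags joined chromosome 13 positions 56298451 to 56299584 and 56367341 to 56369517, with 72 tags over 69.4 kb. The next were on chromosome 5 (114910912 to 114911969 with 115058031 to 115059518, 51 tags), chromosome 14 (41792017 to 41792967 with 41846323 to 41847455, 47 tags), chromosome 10 (79387509 to 79389667 with 79420562 to 79421347, 41 tags) and chromosome 15 (99245853 to 99247786 with 99301045 to 99302242, 40 tags).

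The strongest shared interaction lay on chromosome 14, between 103410668 to 103412482 and 103450300 to 103451403, with 259 wild-type and 256 mutant tags. A chromosome 2 interaction (32259653 to 32261679 with 32342190 to 32344911) had 103 and 108 tags, and a chromosome 3 interaction (145720822 to 145721854 with 145840288 to 145841722) had 95 and 106. The other pair of named shared interactions had more tags in the mutant library. On chromosome 1 (183818297 to 183820330 with 184044964 to 184046546) there were 93 wild-type and 178 mutant tags, with an adjusted p of 0.00344 by the binomial test. On chromosome 11 (4118701 to 4121159 with 4157632 to 4159579) there were 75 and 138 tags, with an adjusted p of 0.0420.

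Interactions in the mutant list spanned longer distances. The median span was 131 kb in the wild-type list and 153 kb in the mutant list, a log2 ratio of 0.23 (95% block interval 0.19 to 0.26). Interactions of 400 kb or more made up 11.7% (11.2 to 12.3) of the wild-type list and 15.2% (14.6 to 15.9) of the mutant list. Those under 100 kb made up 39.6% and 33.9%. The median was 127 kb for interactions of the wild-type list only, 134 kb for shared interactions and 173 kb for those of the mutant list only. Within shared interactions, tags scaled to all listed tags were lower in the mutant under 50 kb (log2 ratio -0.10, block interval -0.18 to -0.04). They were higher at 100 to 200 kb (0.10, 0.04 to 0.15), at 200 to 400 kb (0.12, 0.05 to 0.19) and from 800 kb (0.25, 0.07 to 0.42, 98 interactions). The interval reached both signs at 50 to 100 kb (0.05, -0.02 to 0.11) and at 400 to 800 kb (0.09, -0.004 to 0.18). Shared interactions as a whole held 61.3% of the wild-type and 63.8% of the mutant listed tags. This scaling therefore shifts every span class of shared interactions towards the mutant. The class under 50 kb was lower despite that shift. Whether the higher classes rose beyond shared interactions as a whole was not tested. Among the interactions that passed the binomial test the spans were close, with a median of 112 kb for those higher in the wild-type library and 108 kb for those higher in the mutant library.

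**Figure D2:**
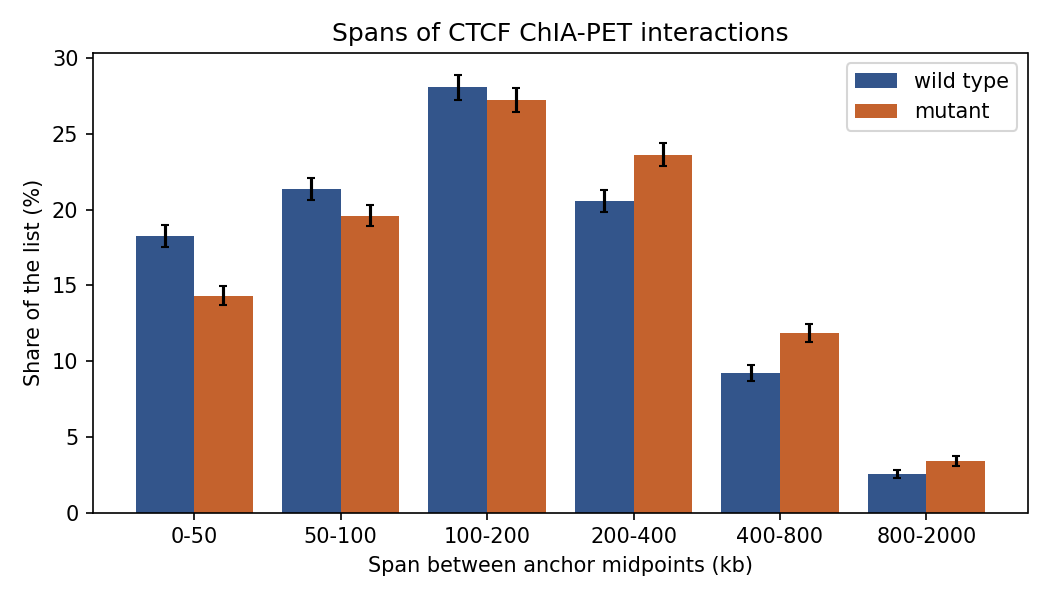
Share of each list (y axis, %) by the distance between anchor midpoints (x axis, kb), with 95% Wilson intervals, for the wild-type and mutant lists. The wild-type list had the larger share under 50 kb, 18.3% against 14.3%, and the mutant list the larger share from 400 to 800 kb, 11.9% against 9.22%.

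Anchors with several partners tended to reach to 1 side. Of anchors with 3 or more partners, 66.4% (64.4 to 68.3) of 2303 were one-sided in the wild-type list and 57.5% (55.6 to 59.3) of 2810 in the mutant list. Random sides would give 19.1% and 18.0%. The mutant share was lower by a difference of -8.92 percentage points (block interval -11.0 to -6.92), and of -7.18 points (-9.24 to -5.27) at the same number of partners. Of 1291 anchors with 3 or more partners in both lists, 597 were one-sided in both, each to the same side. A further 226 were one-sided in the wild-type list only and 105 in the mutant list only. For an anchor one-sided in both lists, a partner found in both forces the same side. The agreement of sides is therefore not an independent result.

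**Figure D3:**
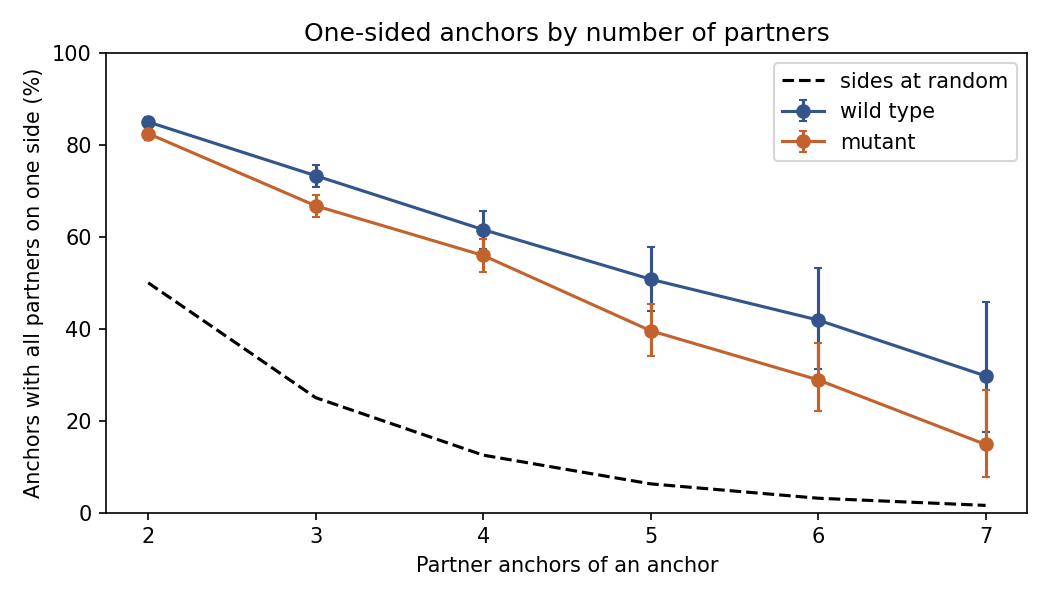
Share of anchors whose partners all lie on 1 side (y axis, %) by the number of partner anchors (x axis), with 95% Wilson intervals; the dashed line gives the share with sides drawn at random. At 3 partners the share was 73.3% in the wild-type and 66.8% in the mutant list, and at 5 partners 50.8% and 39.6%.

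The anchor with most partners in the wild-type list, on chromosome 18 (75758907 to 75760424), had 12 partners, all to its left; in the mutant list it had 10 to the left and 1 to the right. The next were on chromosome 14 (54847143 to 54848594), with 11 wild-type and 12 mutant partners, and on chromosome 3 (121587374 to 121588607), with 10 and 8. The chromosome 14 anchor also led the mutant list. A chromosome 3 anchor (144382835 to 144384208) had 11 mutant partners, 7 to the left and 4 to the right, and 5 wild-type partners, all to the left. A chromosome 1 anchor (182198078 to 182199607) had 11 mutant partners, 2 to the left and 9 to the right, and 6 wild-type partners, all to the right.

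CTCF peaks of wild-type CH12 cells lay at both anchors of 97.8% (97.6 to 98.1) of wild-type and 98.1% (97.8 to 98.3) of mutant interactions, against at most 0.347% for shifted peaks. The difference was 0.238 percentage points (block interval -0.112 to 0.602), and the authors' mapping of interactions to CTCF peaks largely fixes these shares. Counting only peaks at or above the median score gave a difference of 2.66 points (1.56 to 3.75). Anchors found in both lists carried stronger peaks, at a median percentile of 79.1 of the authors' score, than anchors of the wild-type list only (62.0) or of the mutant list only (64.6). Peaks at wild-type interactions missing from the mutant list lay lower than those at matched interactions by a difference of medians of -6.68 percentiles (-7.63 to -5.81). These sets held 9446 and 7905 peaks, and a peak at anchors of both kinds of interaction counted in each. The comparison did not take account of tags, with which the matched share also rose. The share of peaks at an anchor of either list rose from 11.0% to 85.9% between the lowest and highest of 10 equal classes by score.

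The last comparison set the CTCF sites of CH12 cells beside those of B cells. Of the CH12 peaks, 89.5% (89.2 to 89.8) overlapped the B cell list, and 58.5% (58.1 to 58.9) of the B cell peaks overlapped the CH12 list. Shifted peaks gave at most 2.97% and 1.97%. The overlap rose with strength, from 64.9% to 99.9% between the lowest and highest of 10 equal classes of the CH12 list and from 17.6% to 95.7% in the B cell list. The median fold over background, the authors' value, was 7.66 for B cell peaks in the CH12 list and 4.62 for the others. The highest CH12 peaks in the B cell list were on chromosome 7 (25385657 to 25386586), chromosome 14 (67830312 to 67831115) and chromosome 3 (96383831 to 96384801). The highest outside it were on chromosome 13 (71387347 to 71388096), chromosome 17 (39979808 to 39985829) and chromosome 10 (84851284 to 84852416). The chromosome 17 peak was far wider than the median CH12 peak of 581 bp, so it may not be a single CTCF site. In the B cell list, the highest shared peaks were on chromosome X (138634466 to 138635688 and 155846990 to 155847850) and chromosome 5 (144098006 to 144098924). The highest without a CH12 peak were on chromosome 8 (8984978 to 8986234) and chromosome X (104184027 to 104184733 and 156425304 to 156426687).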

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

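No paired analysis was possible because there was 1 ChIA-PET library per genotype. Of 44 alternatives, 4 could not move their value (overlap by a larger part of the anchor, since anchors were identical or disjoint, and the moves along anchors). Of the other 40, 20 stayed within the interval of the reported value or, for the count of differing interactions, within 1.5 times, and 20 did not. A change of direction could be scored only for the span ratio and for lost minus kept, and 0 were found. For the other results no reversal was scored. With better supported interactions the list ratio was 0.949, the matched shares 49.9% (wild type) and 47.4% (mutant), and the one-sided mutant share 60.9%. Anchors within 10 kb gave matched shares of 58.1% and 55.9%, and both anchors in the other list 78.6% and 66.6%, by construction higher. The log2 span ratio was 0.18 at 10 or more tags and 0.27 with lists of equal length. The rise with equal lengths was by construction, since the mutant list was shortened by dropping its shortest interactions with 3 tags. CH12 peaks at or above the median score gave 2.66 percentage points for CTCF at both anchors and -3.32 percentiles for lost minus kept. The CH12 share in the B cell list was 90.2% for peaks at or above the median of each list, and centres within 100 bp gave 82.9% and, for B cell peaks, 54.5%. One-sided shares were 44.3% (wild type) and 31.8% (mutant) with 5 or more partners and 52.4% and 45.8% with anchors merged within 5 kb; the mutant share was lower under each. Limiting the binomial test to shared interactions gave 75 interactions against 177, with fewer tested. Elsewhere the cause was not tested. The thinning, the limit of 10 tags, both anchors in the other list, the moves along anchors and the settings of the binomial test were chosen after seeing the data. The limit of 3 tags leaves weak interactions uncounted, so a missing interaction is not shown to be absent. Gene lists at anchors and motif orientation were not run.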

Other observations

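The tests of counting error, of unrelated anchor pairs, of differing peak calls, of passed-over anchors, of the sensitivity of the CH12 peak list and of a partial loss on chromosome 12 were chosen after the results were seen. The patterns were picked after also looking at tags by chromosome, single interactions, one-sided anchors and runs of peaks in both directions, so they are hypotheses. With 1 library per genotype, 3 sources stay open for each difference between the interaction lists. These are the mutation, any other difference between the wild-type and mutant cells, and any difference between library preparations.

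Interactions of the mutant list spanned longer distances. More tags in the mutant library do not account for all of it, since the log2 span ratio was 0.20 (0.17 to 0.24) after thinning, nor does weakly supported noise, since it was 0.18 (0.10 to 0.27) at 10 or more tags; the mutant median was longer on 20 of 20 chromosomes. Interactions that passed the binomial test did not show it, with a median of 112 kb for those higher in the wild-type library and 108 kb for those higher in the mutant library. A candidate explanation for the longer spans is that mutant interactions pass over anchors no longer used. A farther mutant partner was found for 72.7% of ends whose other anchor was missing and 44.3% of those whose other anchor was kept, against 46.7% and 28.1% with the lists exchanged, a difference of differences of 9.86 percentage points (6.19 to 13.4). As a ratio of ratios the value was 0.988 (0.910 to 1.07), so the answer depends on the scale and this explanation cannot be told apart from a general lengthening; the test had been reworded after related values were seen.

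About 53.2% of wild-type interactions were missing from the mutant list. Counting error as the whole cause is argued against, since 9.95% (7.42 to 13.2) of wild-type interactions with 20 or more tags were missing, where equal rates would leave 0.00128%. Unrelated anchor pairs are argued against by the matched share of 46.8%, above the 13.7% reached by moves along the anchors. Peak calls that differ between the lists cannot be the whole cause, since 24.0% (22.98 to 25.12) of the missing wild-type interactions, and 16 of the 41 with 20 or more tags, had both anchors in the mutant list. For the other missing interactions a differing peak call may be the cause, and near 3 tags counting error stays open as part of the loss.

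The longest run of strong B cell CTCF peaks without a CH12 peak, found by a scan of the genome, held 22 peaks on chromosome 12 from 115286121 to 116559450. Strong here meant only at or above the median −log10 q of the B cell list (29995 of 59978 peaks). An evenly lower sensitivity of the CH12 list is argued against, since random orders of the peaks gave at most 8, but 11 runs of 8 or more were found, so uneven sensitivity stays open. The run held 1 CH12 peak, over a weaker B cell peak, and 0 anchors and 0 interactions of either list. That 1 peak met the bound set beforehand against loss of the whole region in the CH12 line, but at a score of 104 in a list that starts at 90.0 it excludes nothing, a judgement made after it was seen. Loss of all or part of the region may explain the run and cannot be told apart from absent binding: the longest stretch without a CH12 peak was 1112 kb, but the region was picked for lacking peaks.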
